A study of Mus musculus with 8 samples.

How the data were processed

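Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map SMC1, a core subunit of the cohesin ring, in cultured mouse cortical neurons. The 8 samples fell into 4 groups of 2: SMC1 ChIP and its input DNA from resting cultures, and SMC1 ChIP and its input DNA from cultures given NMDA, an agonist of the NMDA class of glutamate receptor. Groups were taken from the antibody and treatment labels, and replicate numbers from the sample titles. The labels call the replicates biological. They do not say whether the cultures came from separate litters. The growth protocol also describes etoposide, but the treatment label of no sample names it.

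FastQC, Trimmomatic, BWA, SAMtools and MACS2 and the mouse builds mm10 and GRCm38.p6 were named, without versions, per the submitters' processing notes. Their settings are not given in the sources used here. The authors deposited 1 peak list per condition, with 20 columns and no header, in the layout that the irreproducible discovery rate (IDR) tool writes. Each line of a deposited list carries the −log10 p of the peak caller in each of the 2 replicates, and a further value that equals their sum on every line. The deposited lists also carry an IDR score scaled up to 1000 and the −log10 of the local and global IDR. The lowest global value in each list corresponded to an IDR of 0.05, so a listed peak had been seen in both replicates and had passed that limit. Peaks that failed it, and peaks seen in 1 replicate, were not analysed here. The field for fold enrichment holds a placeholder in both deposited lists. The design fixed before the data were examined had named fold enrichment as the measure of peak strength, and the summed −log10 p was used in its place. A −log10 p grows with the depth of a library as well as with enrichment. The depth of each library is unknown from these files, so strengths were ranked, filtered and tested within a list only. Values of both lists set side by side, and their ratio at shared peaks, are descriptive and show no change in binding. The replicate columns carry no replicate numbers. Values of the input libraries were not used here except as far as the authors' peak calling used them.

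Peaks of both lists were called shared when they overlapped by at least 1 bp. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Chance overlap was set by shifting the NMDA peaks at random along their own chromosome 1000 times, which does not keep regional differences in peak density. Strength and width of shared and other peaks were compared with two-sided permutation tests of the median log2 value with 100000 resamples. Gene positions came from a RefSeq gene table of GRCm38.p6 that gives the start and end of 49997 genes, without strand, exons or sequence. The planned promoter class was therefore replaced by a gene boundary class, a peak midpoint within 1 kb of either end of an annotated gene, so starts and ends of genes could not be separated. Other peaks inside a gene were called gene body and the rest intergenic, with no division into exons and introns. The planned search for the CTCF motif needs the genome sequence and was not run. Classes of peaks were compared with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 9 tests. A permutation test within deciles of resting strength compared boundary peaks with other peaks of like strength.

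The 15 gene lists were fixed before the data were examined: early response, late response, glutamate receptors, clustered protocadherins, Hox clusters, imprinted genes, cohesin and CTCF, excitatory, inhibitory and pan-neuronal genes, and markers of astrocytes, the oligodendrocyte lineage, microglia, endothelial cells and progenitors. A gene had a peak when one lay within 10 kb of its body. Lists were compared with all other protein-coding genes, 21900 in all with the list, by two-sided Fisher's exact tests. Benjamini-Hochberg adjustment covered 30 tests, 15 lists in 2 conditions. The share of genes with a resting peak that also had an NMDA peak was tested likewise, in a separate family of 15 tests. Named peaks are the 10 strongest of the shared, resting-only and NMDA-only classes. Named genes are those of the 2 response lists with a peak (at most 12 each, by strength), and up to 4 genes of each other list with the strongest peak. Names beyond this rule were chosen after their values were seen: Junb, Egr4, Ccn1, Nr4a2, Btg2, Vgf, Scg2, Grin1, Grin2c, Grin2d, Grin3a, Gria3, Ctcf, Esco1, Esco2, Pcdhac2 and Pcdhgc3. Not every gene that the rule selects is printed. Peaks and neighbouring genes are not replicates of a condition. With 1 list per condition, all p-values describe these lists, and no p is given for the difference in peak number. A comparison of 2 with 2 replicate values could not go below an exact p of 0.33.

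The scripts were tested on simulated data. For the comparison of boundary with other peaks, planted odds ratios of 1, 2 and 4 among 12359 simulated resting peaks were estimated at 0.99, 2.00 and 4.03, and 3.5% of 200 runs without an effect were called. For the overlap, a simulated NMDA list of 1684 peaks with 50% placed on resting peaks gave 51.0%. A list with none placed, moved 2 to 3 Mb, gave 1.78% against 0.96% by shifts, so the shifts gave a lower chance overlap than this 1 simulated list. For the gene lists, 20 genes with 35 points added to the share with a peak were called in 87.4% of 500 runs over 21900 genes, against 3.2% with none added. These calls used an unadjusted p on genes drawn at random. The shares do not carry over to calls after Benjamini-Hochberg adjustment or to lists of clustered or long genes. For the strength comparison over 12359 peaks, 3.0% of 200 runs without a shift were called and 97.5% with a log2 shift of 0.1.

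The alternatives fixed before the data were examined were reciprocal overlap, a gap of 500 bp, a stricter IDR of 0.01, the peaks of each list at or above its median strength, equal list lengths, autosomes only, other measures of strength, other distances to genes, protein-coding genes only, strata of gene length and of strongest peak, gene clusters counted once, and single replicate columns for the ratio of NMDA over resting strength. Strata of peak width, midpoint distance, removal of peaks with a strength above 300, distance to gene ends and single replicate columns for the overlap, strength and boundary results were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used, with a random seed of 11 as the base.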

Results

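SMC1 ChIP-seq was compared between resting mouse cortical neurons at day 13 in vitro and neurons exposed to 50 µM NMDA for 10 min and collected after 50 min in drug-free medium. Bath NMDA opens calcium-permeable glutamate receptors throughout the culture. SMC1 belongs to cohesin, the ring complex that extrudes chromatin loops and is often halted by the insulator protein CTCF. Each condition had 2 ChIP and 2 input samples, and 1 list of peaks found in both ChIP replicates. Positions are on GRCm38. Library depths are unknown from the lists, and peak strength is the authors' −log10 p summed over the 2 replicates.

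The first comparison asked how far the reproducible SMC1 sites of resting and NMDA-treated neurons coincide. The resting list held 12359 peaks and the NMDA list 1684, a ratio of 7.34. At an IDR up to 0.01 they held 7037 and 350, a ratio of 20.1. Most NMDA peaks lay at resting sites: 1277 of 1684 overlapped a resting peak (75.8%, 95% interval 73.7 to 77.9%). In the other direction 1321 of 12359 resting peaks overlapped an NMDA peak (10.7%, 10.1 to 11.2%), leaving 11038 resting-only peaks. The other 407 NMDA peaks were NMDA-only, and 47 of these had a resting peak within 5 kb.

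Randomly shifted NMDA peaks met a resting peak in 0.97% of cases on average and at most 2.02%, so the overlap exceeded chance (permutation of positions, p = 0.001, the smallest they can give). The resting list covered 9157 kb with a median peak width of 644 bp, and the NMDA list 1897 kb with a median width of 1033 bp. Peak strength had a median of 30.2 in the resting list and 23.0 in the NMDA list. Across peaks, which are not independent replicates, the replicate columns had a Spearman correlation of 0.43 in the resting list and −0.21 in the NMDA list. The Pearson correlation of their log values was 0.51 and 0.22. Only peaks that had passed in both replicates enter these values, so they do not measure how well the libraries agree. When the resting list was reduced to its strongest 1684 peaks, 29.5% of NMDA peaks overlapped it, and with both lists at an IDR up to 0.01, 4.09% of resting peaks were shared.

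Resting sites that were also found after NMDA were the stronger and wider ones. The strongest shared sites at annotated genes included the boundary of Ptpre, a receptor-type tyrosine phosphatase, on chromosome 7 at 135537145 to 135538331 (resting strength 285). They also included the boundary of Arhgap22 on chromosome 14 at 33213532 to 33214358 (221), and that of the sorting nexin gene Snx18 on chromosome 13 at 113617443 to 113619181 (188). Further strong shared sites lay inside Col27a1 (193), a fibrillar collagen gene, and inside Kcnh1 (174), a voltage-gated potassium channel gene. Others lay nearest to the translation initiation factor gene Eif4b (226) and to Hif1an (176), which encodes a hydroxylase acting on hypoxia-inducible factor. The boundary of Csrp1 held a further one (173). The top shared site, at 98666955 to 98667301 on chromosome 2, stood far apart with a strength of 3610 and lay 35.5 kb from the nearest annotated gene end. The NMDA peak over it had 21863, against list medians of 30.2 at rest and 23.0 after NMDA. No region prone to artefact signal was removed here, and whether this site holds SMC1 was not tested.

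Shared resting peaks had a median strength of 42.8 (n = 1321 peaks) and resting-only peaks 29.4 (n = 11038), a log2 difference of 0.54 (permutation test, p = 1e-05, the smallest they can give). Their median widths were 1006 and 618 bp (permutation test, p = 1e-05). The shared fraction was 5.02% in the weakest decile of resting peaks (95% interval 3.87 to 6.38%) and 33.4% in the strongest (30.8 to 36.1%). Of the 100 strongest resting peaks 73 were shared, and of the 500 strongest 237 (47.4%).

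Strong resting sites without an NMDA peak were also present. The strongest was on chromosome 1 at 155006465 to 155007059, with a strength of 240 and 1930 bp from the end of the noncoding gene Gm41977. Others lay inside Krt78 (161), a keratin gene, and Acox3 (143), a peroxisomal oxidase gene, and near Sost (142), an inhibitor of Wnt signalling, Mmp2 (139), a matrix metalloproteinase, and Zbp1 (139), a nucleic acid sensor. The site at Nr6a1 (125) was the 1 of the 10 strongest resting-only peaks at a gene boundary. Those near Atp9a (125) and Sorl1 (125) were not.

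Among NMDA peaks, shared ones had a median strength of 23.9 and NMDA-only ones 21.4, a log2 difference of 0.15 (permutation test, p = 1e-05), while their widths of 1036 and 1026 bp were not separated (permutation test, p = 0.748). At the 1321 shared resting peaks the replicate columns had medians of 22.0 and 20.2 in the resting list and 13.4 and 10.1 at the matching NMDA peaks. The median log2 ratio of NMDA over resting was −0.79 for the summed values. Over the 4 pairings of single columns it lay between −1.10 and −0.53. Across these peaks the resting columns had a Spearman correlation of 0.66 with each other, and the NMDA columns one of −0.14. The first NMDA column had 0.31 and 0.26 with the resting columns, and the second 0.013 and −0.015. The second NMDA column thus did not follow the order of strength at rest, which limits the NMDA strengths and the ratios. The ratios also depend on library depth and were not tested.

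The next comparison placed the peaks relative to genes. SMC1 peaks found after NMDA lay mainly at the ends of genes, and those found at rest alone mainly elsewhere. Of NMDA-only peaks 79.6% (95% interval 75.4 to 83.4%, n = 407) had a midpoint within 1 kb of an annotated gene end, and of shared NMDA peaks 55.8% (53.1 to 58.6%, n = 1277). The share was 54.7% in shared resting peaks (52.0 to 57.4%, n = 1321) and 25.9% in resting-only peaks (25.1 to 26.7%, n = 11038). Resting-only peaks were in gene bodies in 41.4% of cases and intergenic in 32.7%, and NMDA-only peaks in 15.7% and 4.67%.

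**Figure D1:**
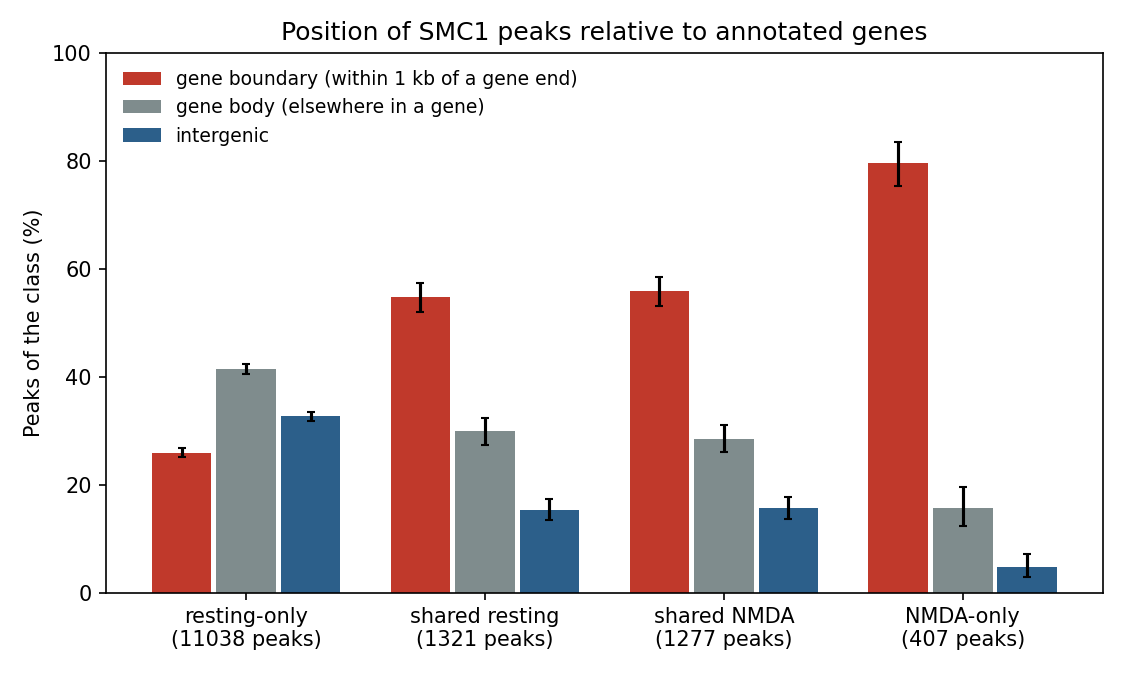
Percent of peaks (y axis) at a gene boundary, in the rest of a gene and between genes, for the 4 classes of SMC1 peak (x axis, with the number of peaks); lines on the bars are exact 95% intervals over peaks. Boundary peaks made up 25.9% of resting-only and 79.6% of NMDA-only peaks.

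The NMDA-only peaks at gene boundaries included those at Yy1, a zinc finger protein that binds promoters and enhancers (chromosome 12, 108792060 to 108793293, strength 36.5), and at Tead1, the DNA-binding partner of YAP (chromosome 7, 112677705 to 112679429, 35.5). They also included Faf2 (34.7), the mitochondrial NAD kinase gene Nadk2 (32.8), Agrn (32.7), which encodes the synapse organiser agrin, Ptar1 (32.6) and Mphosph10 (31.6), a gene for a nucleolar protein of ribosome production. These 7 were among the 10 strongest NMDA-only peaks. The other 3 were a pair on chromosome 2, at 98662239 to 98662938 (396) and 98664851 to 98665406 (277), close to the top shared site, and 1 on chromosome X 35.3 kb from Pak3 (96.4). As at that shared site, whether the pair on chromosome 2 holds SMC1 was not tested.

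By Fisher's exact test, gene boundaries were more frequent in shared than in resting-only resting peaks (odds ratio 3.46, adjusted p = 3.07e-95) and in NMDA-only than in shared NMDA peaks (odds ratio 3.09, adjusted p = 1.84e-18). They were also more frequent in NMDA-only than in resting-only peaks (odds ratio 11.2, adjusted p = 9.00e-108, exact test). Shifted peak positions placed 6.45% of resting and 6.51% of NMDA peaks at gene boundaries, against 29.0% and 61.6% observed in the whole lists. An NMDA peak overlapped 723 of 3584 resting boundary peaks (20.2%) and 598 of 8775 other resting peaks (6.81%). Among peaks of like resting strength the odds ratio was 4.57 (95% interval 4.02 to 5.19, permutation test within deciles, p = 1e-05), and the share was higher at boundaries in 10 of 10 deciles. With strata of peak width added, a choice made after seeing the data, it was 2.56 (2.23 to 2.93).

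**Figure D2:**
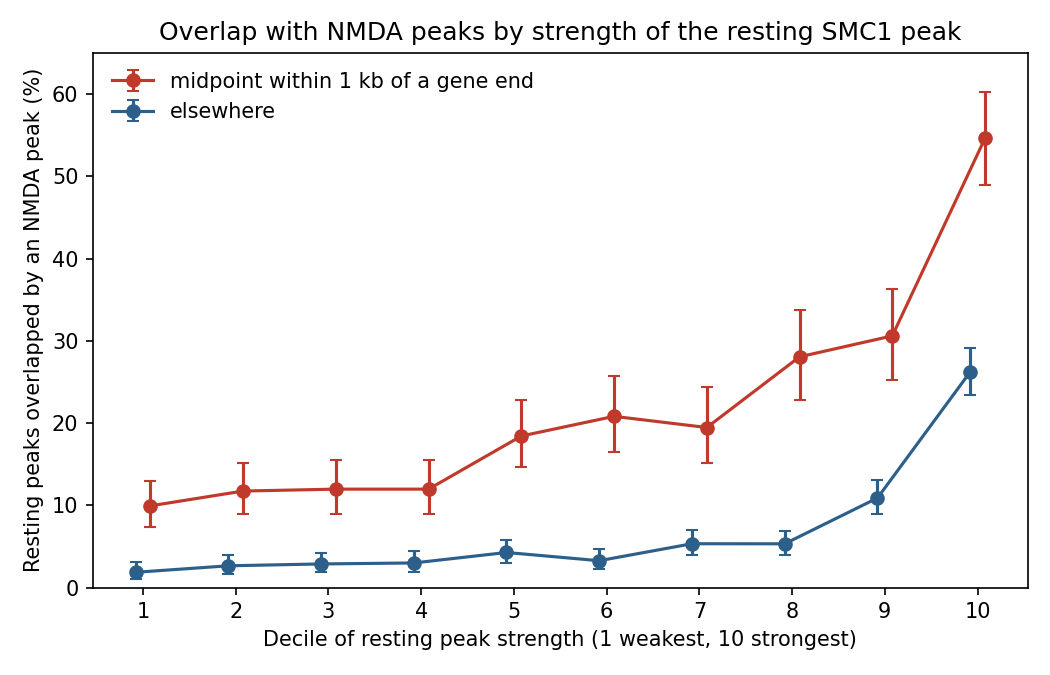
Percent of resting SMC1 peaks overlapped by an NMDA peak (y axis) in each decile of resting peak strength (x axis), for peaks at gene boundaries (red) and elsewhere (blue); vertical lines are exact 95% intervals over peaks. In the strongest decile the shares were 54.6% at boundaries and 26.2% elsewhere, and in the weakest 9.94% and 1.86%.

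Genes of the neuronal activity response were examined next, since NMDA drives their transcription. Early response genes often had SMC1 peaks in both conditions. A resting peak lay within 10 kb of 16 of 22 (72.7%, against 38.2% of all protein-coding genes), and an NMDA peak within 10 kb of 9 of 22 (40.9%, against 8.94%). Of the 16 with a resting peak 8 also had an NMDA peak (50.0%, against 19% of all genes with a resting peak). Late response genes had a resting peak in 14 of 20 cases (70.0%) and an NMDA peak in 3 of 20 (15.0%).

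The 8 early response genes with both were the AP-1 genes Fosb and Jun, the transcription factor genes Npas4, Egr2, Nr4a1 and Nr4a3, the growth arrest gene Gadd45b and the phosphatase gene Dusp1. The site near Fosb lay on chromosome 7 at 19300284 to 19301409, 1849 bp from the gene's end, with a resting strength of 122, and the NMDA peak there had 18.6. At Npas4, an activity-dependent factor selective for neurons, the resting peak on chromosome 19 at 5001757 to 5002456 had a strength of 116 and the overlapping NMDA peak 25.2. The Jun site on chromosome 4 at 95049974 to 95052543 had 72.0 in the resting list and 55.4 in the NMDA list. Gadd45b had 97.2 and 28.9, Nr4a1 70.6 and 29.9, and Dusp1 51.4 and 19.4. At Egr2 the strongest peaks of the lists were at different positions, with 95.4 at rest and 22.5 after NMDA.

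A resting peak without an NMDA peak was found at Fos (chromosome 12, 85473056 to 85475083, strength 48.1) and at Egr1 (chromosome 18, 34859798 to 34861976, 51.3), and at Junb, Atf3, Klf4, Egr4, Btg2 and Ccn1 with 20.1 to 28.1. Nr4a2 had only an NMDA peak (20.7), inside the gene. Among late response genes, the stress peptide gene Crh had 90.7 at rest and 28.4 after NMDA, the synaptic scaffold gene Homer1 55.3 and 24.2, and the kinase gene Pim1 30.8 and 21.2. The other 11 late response genes with a resting peak had no NMDA peak. They were the cell cycle inhibitor gene Cdkn1a (91.5), the G protein signalling regulator gene Rgs2 (70.7), Rasgrp1 (55.0), Plk2 (54.9), Inhba (34.96), Mylip (34.2), Sorcs3 (31.2), the neurotrophin gene Bdnf (31.0, inside the gene), Gpr3 (20.9), Vgf (19.4) and Scg2 (18.6).

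Early response genes differed from other genes by Fisher's exact test for resting peaks (odds ratio 4.32, adjusted p = 0.0109), for NMDA peaks (7.08, adjusted p = 0.00181) and for the share with both (4.27, adjusted p = 0.0253). Late response genes differed for resting peaks (3.78, adjusted p = 0.0208), but not for NMDA peaks (adjusted p = 0.569) or the share with both (3 of 14, adjusted p = 1) by the same exact test. The early response calls for NMDA peaks and for both ended when genes were matched on their strongest resting peak (permutation tests, adjusted p = 0.0872 and 0.182). The resting calls of both lists ended with peaks up to 50 kb away (Fisher's exact test, adjusted p = 0.106 and 0.241). The differences were then 24.0 and 17.7 points, against 34.5 and 31.8 within 10 kb. The early response call for both ended within 2 kb of gene ends (exact test, adjusted p = 0.244), where the difference was 24.7 points against 31.0. The other genes were not matched for expression. They include 1110 olfactory receptor genes, of which 2.16% had a resting peak. The calls therefore do not set response genes apart from expressed genes in general.

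Genes for glutamate receptors, which include the subunits of the NMDA receptor itself, were tested as a further group. SMC1 lay near 16 of 23 at rest (69.6%) and near 7 of 23 after NMDA (30.4%), all of the 7 among the 16. The kainate receptor gene Grik4 had the strongest site, at its boundary on chromosome 9 at 42943765 to 42945092 (97.3 at rest, 46.4 after NMDA), followed by the metabotropic receptor gene Grm8 (73.2 and 24.7). The NMDA receptor subunit genes Grin2a (72.4 and 22.9), and Grin2c and Grin3a, had peaks in both lists, Grin2b (64.0) and Grin2d (46.8) had resting peaks only, and Grin1 had none in either list. Differences from other genes passed for resting peaks (adjusted p = 0.0201, Fisher's exact test) and NMDA peaks (adjusted p = 0.0184, Fisher's exact test), and the share with both did not (adjusted p = 0.0512, Fisher's exact test). Receptor genes are long, and among genes of like length both calls ended (permutation tests, adjusted p = 0.751 and 0.204). The resting call also ended with peaks up to 50 kb away (exact test, adjusted p = 0.156), and the NMDA call among genes of like strongest resting peak (permutation test, adjusted p = 0.189).

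Clustered gene families had SMC1 peaks at rest and none within 10 kb after NMDA. The clustered protocadherins, cell-surface identity molecules chosen through CTCF and cohesin looping, had a resting peak near 34 of 57 genes (59.6%) and an NMDA peak near none. The region on chromosome 18 from 36930285 to 37841873 held 5 resting peaks, and the 34 genes rested on 3 of them, at the boundaries of Pcdhac1 (49.8), Pcdhac2 (18.1) and Pcdhgc3 (32.7). The other 2 lay between the Pcdha and Pcdhb genes, more than 10 kb from any gene of the list, and included the strongest, at 37217872 to 37219007 with a strength of 73.8. The nearest NMDA peak, at 37852065 to 37852612, was 10.2 kb beyond the region and overlapped a resting peak with a strength of 92.0. Hox genes, which pattern the body axis, had a resting peak near 26 of 39 (66.7%), among them Hoxd13 (69.9), Hoxa9 and Hoxa7 (60.8, the same peak for both genes), and no NMDA peak.

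**Figure D3:**
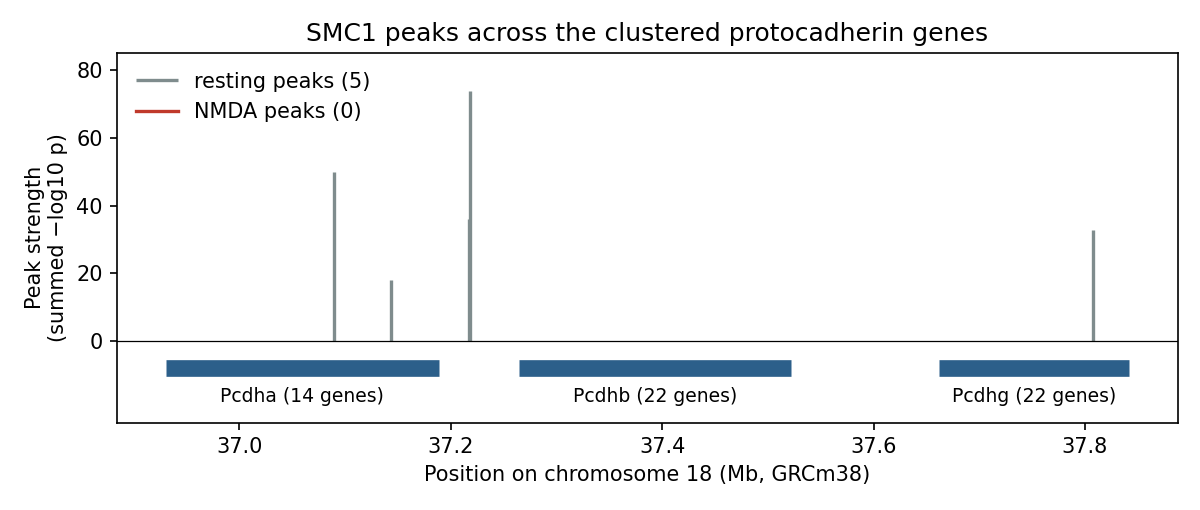
Resting SMC1 peaks (grey lines) drawn at their position on chromosome 18 (x axis, Mb) with their strength as summed −log10 p (y axis); blue bars span the 3 protocadherin gene clusters. The region held 5 resting peaks and 0 NMDA peaks.

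By Fisher's exact test over genes, protocadherins differed for resting peaks (adjusted p = 0.0109), NMDA peaks (adjusted p = 0.0263) and the share with both (0 of 34, adjusted p = 0.0217). Hox genes differed for resting peaks (adjusted p = 0.00595) and the share with both (0 of 26, adjusted p = 0.0282), not for NMDA peaks (adjusted p = 0.106), by exact test. Counting each cluster once ended all 5 calls (exact tests, adjusted p from 0.0797 to 1). A cluster then counts as having a peak when any of its genes does. The resting differences rose to 61.8 points for Hox (from 28.5) and 28.5 for protocadherins (from 21.5). Those for both stayed at −19.1 points in each list, and that for protocadherin NMDA peaks at −8.96. With so few units, the lost calls do not show that the differences are gone. Matching on gene length ended the protocadherin resting call and the Hox call for both (permutation tests, adjusted p = 0.327 and 0.0512). From their strength 0.70 of the 5 peaks in the protocadherin region were expected to be shared, and 0 were (permutation test within strength deciles, p = 0.588). With so few expected, this test could not have shown a deficit. Within 50 kb the direction turned for protocadherins, which lay 20.0 points above other genes for NMDA peaks and 33.8 points above for both, and within 2 kb of gene ends their resting share lay 13.7 points below that of other genes. The Hox resting call also ended within 2 kb, at 6.72 points (exact test, adjusted p = 0.571). Matching on strongest resting peak ended the protocadherin call for both (permutation test, adjusted p = 0.0519).

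Genes for cohesin and CTCF themselves had a resting peak in 7 of 15 cases (46.7%) and an NMDA peak in 5 of 15 (33.3%), so 5 of the 7 had both (71.4%). These were Ctcf (21.5 at rest, 27.6 after NMDA), the cohesin subunit genes Stag1 (136 and 41.8) and Smc3 (40.1 and 19.1), the cohesin loader gene Nipbl (52.2 and 23.9) and the acetyltransferase gene Esco1 (28.1 and 26.97). Pds5b (35.5) and Esco2 had resting peaks only. Fisher's exact test separated them from other genes for NMDA peaks (adjusted p = 0.0263) and for both (adjusted p = 0.0253), not for resting peaks (adjusted p = 0.746). The NMDA call ended among genes of like length (permutation test, adjusted p = 0.119). It also ended with peaks up to 50 kb away (exact test, adjusted p = 0.106), with a difference of 23.2 points against 24.4. Both calls ended within 2 kb of gene ends (exact tests, adjusted p = 0.169 and 0.244). There the NMDA difference was 14.0 points against 24.4 and the difference for both 53.0 points against 52.4.

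The imprinted list and most cell type lists were not separated from other genes. Imprinted genes had resting peaks in 10 of 17 cases and NMDA peaks in 3 of 17, at Gnas (119 at rest, 40.6 after NMDA), Kcnk9 and Mest. Excitatory neuron genes had 9 of 15 and 2 of 15, with Bcl11b, a cortical projection neuron factor, in both lists (73.3 at rest, 30.9 after NMDA). Inhibitory neuron genes had 6 of 15 and 0 of 15, led by Sst (79.7) and Gad1 (60.03), and pan-neuronal genes 8 of 17 and 1 of 17, the latter at the tau gene Mapt. Astrocyte genes had 7 of 11 and 1 of 11, oligodendrocyte lineage genes 6 of 9 and 3 of 9, and endothelial genes 1 of 6 and 0 of 6. None of these 7 lists passed Fisher's exact test after adjustment in any of the 3 comparisons (adjusted p from 0.0993 to 1). Their resting shares ran from 16.7% for endothelial genes to 66.7% for the oligodendrocyte lineage, against 38.2% of all protein-coding genes. The Hox list passed at the same 66.7%, with 39 genes. With 6 to 17 genes in a list, a missing call does not show that the list is like other genes.

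Progenitor genes had resting peaks in 7 of 8 cases (87.5%, adjusted p = 0.0238, Fisher's exact test), led by the Notch target Hes1 (107.4), Eomes (69.6) and Pax6 (55.0). NMDA peaks lay near 3 of 8 (adjusted p = 0.0772, exact test), and 3 of the 7 had both (adjusted p = 0.282, exact test). Microglial genes had 3 of 10 in both lists (resting adjusted p = 0.866, NMDA adjusted p = 0.114, both 0.0258, exact tests), the complement genes C1qa, C1qb and C1qc, which share 1 NMDA peak, so that call rests on 1 site. With peaks up to 50 kb away the progenitor and microglial calls ended (exact tests, adjusted p = 0.481 and 0.164).

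**Figure D4:**
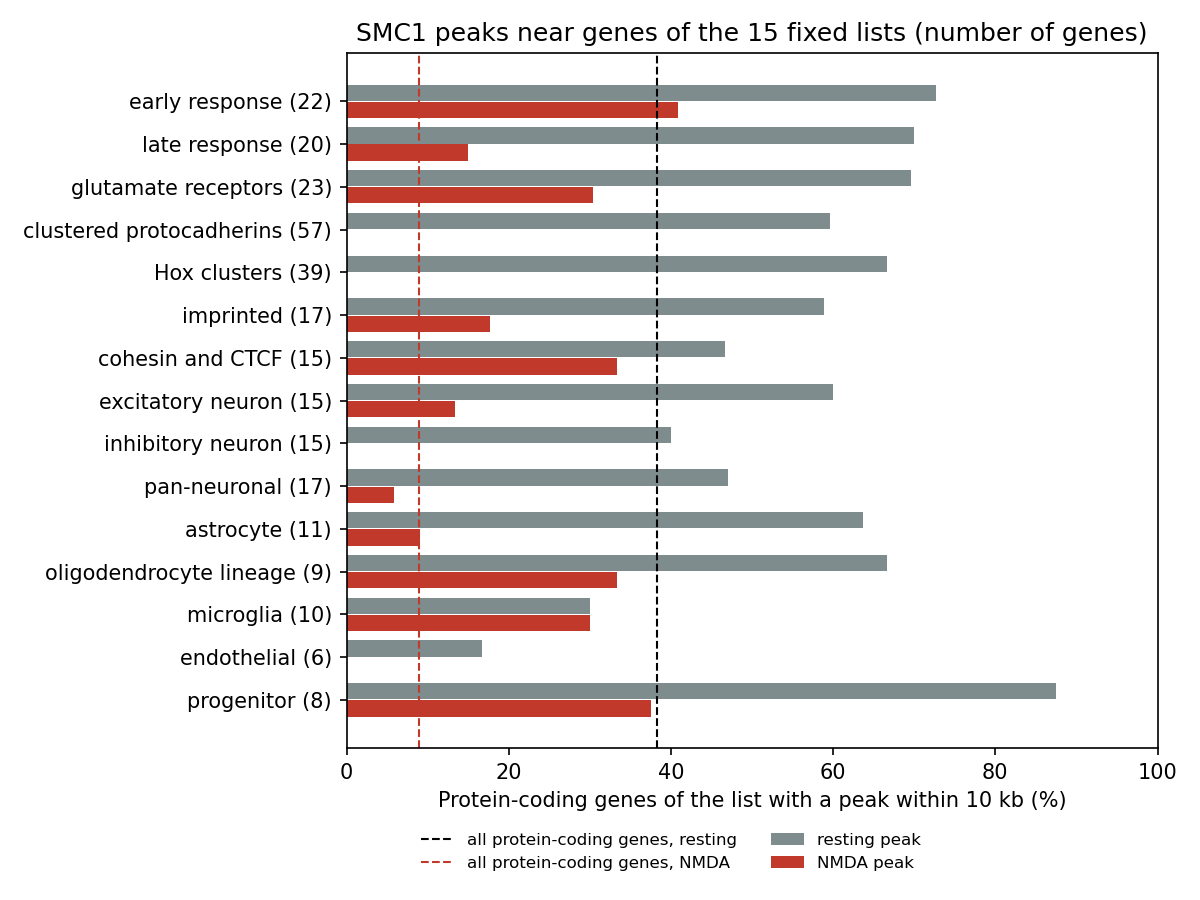
Percent of protein-coding genes of each of the 15 lists (y axis, number of genes in parentheses) with a resting (grey) or NMDA (red) SMC1 peak within 10 kb (x axis); dashed lines are the shares of all protein-coding genes, 38.2% at rest and 8.94% after NMDA. Bars carry no error since each is 1 count from 1 list; the early response list reached 72.7% and 40.9%, and the protocadherin and Hox lists 0 for NMDA.

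Peaks were spread over all autosomes and were sparse on the X chromosome. X held 114 of 12359 resting peaks (0.92%) and 5 of 1684 NMDA peaks (0.30%), but 4.41% of protein-coding genes. That is 11.8 resting peaks per 100 protein-coding genes on X, against 38.8 on chromosome 7, the autosome with the fewest. A resting peak lay within 10 kb of 70 of 966 X-linked genes (7.25%) and 40.2% of autosomal genes, and the glutamate receptor gene Gria3 was among the X-linked genes with one. None of the 114 resting peaks on X was shared, against 10.7% of all resting peaks (Fisher's exact test, adjusted p = 8.87e-05 over 20 chromosomes). Resting peaks on X were weaker than on autosomes (median 23.8 against 30.3) and less often at gene boundaries (19.3% against 29.1%). The resting decile that holds 23.8 shared 5.83%. No test on X was matched for strength, so 10.7% is too high an expectation. With 5 NMDA peaks on X, few of the 114 resting peaks could have been shared, so the test largely restates that scarcity. On chromosome 8 the shared fraction was 14.6% (adjusted p = 0.0179, exact test), and no other chromosome passed (adjusted p from 0.354 to 1, exact tests). Among resting peaks at or above the median strength, X held 0.37%.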

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

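Width strata, midpoint distances, distance to gene ends, removal of extreme peaks and, except for the ratio of NMDA over resting strength, single replicate columns were chosen after seeing the data. The differences in strength and gene boundary shares, and the boundary odds ratio (2.56 to 5.21), kept direction and side of the threshold under every alternative run. The ratio of peak numbers, 7.34 as reported, was 20.1 at an IDR up to 0.01. The share of NMDA peaks that overlapped a resting peak, 75.8% as reported, was 64.7% with reciprocal overlap, 78.6% at an IDR up to 0.01, 66.3% for peaks at or above their list's median strength, 29.5% with lists of equal number and 55.9% for midpoints within 250 bp. The share of resting peaks was 8.81%, 4.09%, 9.15%, 29.3% and 7.62% in the same order. With peaks at or above the median of a single replicate column, these shares ran from 53.2 to 66.3% and from 7.35 to 8.95%. Both replicates had still set which peaks were listed, so single columns cannot show how far a result depends on 1 replicate. With equal numbers, the shortened resting list leaves NMDA peaks fewer peaks to meet. The median log2 ratio of NMDA over resting strength, −0.79 as reported, was −1.16 for resting peaks at or above the median strength and −1.08 without the first NMDA replicate column. The former selects on the resting strength that the ratio divides by, which in itself lowers the ratio. It shows no greater loss at strong sites. X held 0.37% of resting peaks at or above the median strength. The cause of the other changes was not tested.

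Of the gene lists, 6 differed from other genes for resting peaks, 1 within 50 kb. For NMDA peaks 4 differed, 2 within 2 kb of gene ends and 2 among genes of like length. For both, 5 differed, 0 within 2 kb of gene ends, 3 among genes of like strongest resting peak and 3 with clusters counted once. The protocadherins turned direction, to −13.7 points for resting peaks within 2 kb, 20.0 points for NMDA peaks and 33.8 points for both within 50 kb, where the windows take in other peaks. Over the 15 list calls and 69 alternatives, 37 kept call and direction, 29 kept direction without the call and 3 turned.

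No paired analysis was possible because the replicate columns carry no replicate numbers. The planned omission of a replicate at a list's own lowest value admits every peak and was replaced by the median of 1 column. The motif alternatives and the windows around transcription starts were not run, since they need sequence and strand. Unknown library depth limits every comparison between the lists: a site missing from the NMDA list was not detected at that depth and is not shown to be absent.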

Other observations

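The tests of gene families, transfer RNA genes, width strata and peaks per gene and strength on the X chromosome were chosen after the result was seen. The share of peaks on X was planned. The strength deciles were planned with fold enrichment, and the boundary comparisons took the place of planned promoter comparisons. The use of all 3 to weigh explanations was chosen afterwards. Gene families outside the fixed lists also differed in SMC1 peaks. Families were taken by how the gene symbol starts, so each can take in related genes beyond its name. Genes for potassium channels (Kcn symbols) had a resting peak within 10 kb in 57 of 94 cases (60.6%, against 38.1% of other protein-coding genes, adjusted p = 8.15e-05, Fisher's exact test over 27 tests) and an NMDA peak in 16 of 94 (17.0%, adjusted p = 0.035, exact test). Among genes of like length the resting difference had an unadjusted permutation p of 0.00612 and the NMDA difference one of 0.0946. Calcium channel genes (Cacn symbols) had a resting peak in 17 of 26 cases (65.4%, adjusted p = 0.0282, exact test), a difference lost among genes of like length (permutation test, unadjusted p = 0.537). Zinc finger genes with Zfp symbols had a resting peak in 98 of 397 cases (24.7%, adjusted p = 7.22e-08, exact test), and olfactory receptor genes, which are silent in most neurons, in 24 of 1110 (2.16%, adjusted p = 2.99e-194, exact test). These tests count each gene as 1 unit. Neighbouring genes can share a peak or its absence, and gene clusters were not counted once here, so the p-values may be too small. Whether reads map uniquely in such families was not examined. Translation initiation factor genes (Eif symbols) had NMDA-only peaks near 6 of 56 (10.7%, against 2.68%, adjusted p = 0.0177, exact test), whereas neither their share with any NMDA peak (7 of 56, 12.5% against 8.93%, adjusted p = 0.663, exact test) nor their resting share (37.5%, adjusted p = 1, exact test) passed. Genes with Rpl or Rps symbols are ribosomal protein genes, with the Rps6k kinase genes among them. They did not pass for resting peaks (43 of 97, 44.3% against 38.2%, adjusted p = 0.561) or NMDA peaks (7 of 97, adjusted p = 0.918) by exact test. Among genes of like length their resting share was higher (permutation test, unadjusted p = 0.00044). Proteasome genes (Psma to Psmg symbols, 27 of 51, 52.9%) and GABA-A receptor genes (Gabr symbols, 4 of 19, 21.1%) did not pass for resting peaks before length was matched (adjusted p = 0.114 and 0.387, exact tests). Among genes of like length the first were above and the second below other genes (permutation tests, unadjusted p = 0.00748 and 0.0025). Genes with Nduf symbols, for complex I subunits and assembly factors (18 of 49, 36.7%), did not pass either way (adjusted p = 1, exact test, and unadjusted p = 0.532, permutation test).

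Genes for transfer RNA, short genes read by RNA polymerase III, carried 23 resting peaks, of which 8 overlapped an NMDA peak (34.8%, 95% interval 16.4 to 57.3%). From strength alone 2.63 were expected (permutation test, p = 0.00158), and among gene boundary peaks of like strength 4.95 (permutation test, p = 0.106). The extreme strengths were at 98666169 to 98667551 on chromosome 2 (21863 in the NMDA list) and at 103648903 to 103649549 on chromosome 6 (1083). A further NMDA peak on chromosome 9 at 3018834 to 3019687 had 41.1 in one replicate column and 490.6 in the other. Apart from the alternative without peaks above 300, no such peaks were removed, and whether they reflect SMC1 or artefact signal was not tested. One NMDA peak lay on an unplaced scaffold.

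The resting list held 7.34 times as many peaks as the NMDA list, and 20.1 times as many at an IDR up to 0.01. One loss of sensitivity set by the summed −log10 p alone would leave boundary and other peaks of like strength equally often shared. The odds ratio of 4.57 (95% interval 4.02 to 5.19) argues against that narrow form only. Strata of width lowered it to 2.56, and the replicate columns of the resting list correlated at only 0.43. Strength is thus matched imperfectly, and a technical loss that depends on other properties of a peak is not excluded. Lower depth or enrichment in the NMDA libraries could still shorten the list. The shared fraction was 33.4% in the strongest decile and 5.02% in the weakest, which loss of depth and loss of cohesin would both give. Depth and treatment cannot be told apart, since each condition is 1 list of unknown depth, and a response to NMDA stays open and untested. The length of an IDR list also depends on how well its replicates agree. Over listed peaks the replicate columns had a Spearman correlation of 0.43 at rest and −0.21 for NMDA. The Pearson correlation of their log values was 0.51 and 0.22. These peaks had passed in both replicates, so neither measure gives the agreement of the libraries. The part of replicate agreement in the ratios of peak numbers was not tested, so neither ratio counts lost sites.

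Resting peaks at gene boundaries were shared more often. Boundary peaks may meet an NMDA peak more easily where they are wide. With strata of strength and width the odds ratio was 2.56 (2.23 to 2.93), so width lowers it and, as far as these strata match it, is not the whole cause. General background at open gene ends in the NMDA libraries is another candidate explanation. NMDA-only peaks were at gene boundaries 23.8 points more often than shared NMDA peaks, as such background would give. Cohesin held or loaded at gene ends after NMDA would give the same, and these cannot be told apart without coverage of the input and ChIP libraries.

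The X chromosome held few peaks. Fewer genes on X could not account for it, since X had 11.8 resting peaks per 100 protein-coding genes against 38.8 on the lowest autosome. A single X copy in part of the cells may lower peak strength, and the median strength on X was 23.8 against 30.3 on autosomes. The sex of the embryos is not given in the labels, so this explanation stays open, and other properties of X were not tested.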
